A study of Mus musculus with 24 samples.

How the data were processed

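The deposited files are 24 tables of counts per gene, 1 per library, and a series table of the same counts. Per the labels the submitters used FastQC 0.11.9, cutadapt 2.10, TopHat, SAMtools 1.10, Picard 2.13.2 and HTSeq 0.11.0 with the GRCm39 build, and RNA was taken through the NEBNext low-input kit and sequenced on a NovaSeq6000. The annotation release, the strand setting and the handling of duplicates are not given in the sources used here, and the role of each tool is not stated. The library files hold 53700 genes under 53599 symbols. The series table holds 36982 symbols, all equal to the library files after summing genes of the same symbol, and the 16617 absent symbols had 0 counts in total. The library files were used. The available annotation is of another build, so no positions are given and genes were not checked against it.

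The groups were set from the labels before the data were examined: 3 ages and 2 genotypes, 4 libraries each. The design text says 3 or 4 per condition, and no library is marked as left out. A library of wt at 9 months carries the replicate name 2_4, and its meaning is not given in the sources used here. Replicate numbers were not taken to pair libraries. No animal identities, sorting days or batches are given in the labels.

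Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr by group, TMM factors, a quasi-likelihood fit (robust) of the 6 group means over all 24 libraries, and Benjamini-Hochberg adjustment within each comparison, called at adjusted p under 0.05. This left 15156 genes. The comparisons were tg against wt at each age, the 3 differences of those between ages, and the 3 age comparisons within each genotype. The biological coefficient of variation was 64.6% with all 24 libraries, 67% with 23 and 66% with 22. CPM in the text use TMM factors, and means and SD for tg at 9 months leave out the low-count library. A level under 3 counts in a library (0.211 to 0.368 CPM in 23 libraries, 474 CPM in the low-count library) is called under the floor, and no fold is given where a group's mean lies under it. Fitted folds of genes with some libraries under it, such as Camp and Retnlg, depend on the prior count. Floors and intervals cover counting error only.

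For gene lists, 31 lists of marker and pathway genes were written down from general knowledge before the data were examined, and lists with at least 3 tested genes were used. They cover homeostatic microglia, DAM stages 1 and 2, interferon response, MHC class I and II, complement and Fc receptors, lysosome, lipid handling, cholesterol synthesis, orthologues of Alzheimer risk genes, inflammatory genes, TGF-beta signalling, proliferation, glycolysis, nuclear and mitochondrially encoded respiratory genes, ribosomal proteins, the unfolded protein response, immediate early and circadian genes, and markers of border-associated macrophages, monocytes, neutrophils, lymphocytes, neurons, astrocytes, oligodendrocytes, vascular cells, choroid plexus and erythrocytes. The test was camera (limma 3.58.1) on log2 CPM with a prior count of 3 and a preset correlation of 0.01, adjusted over 31 lists and 3 ages, and in the same way over the 3 age comparisons. Camera asks whether a list differs from the other genes. Camera with an estimated correlation and fry, which asks whether a list differs from no change, are given beside it. Counts adjusted over the list alone take the edgeR p-values of the list's genes. List directions were also counted with RLE factors and library totals, a check added after the data were seen. Between 4 and 9 months in tg the median log2 FC of all genes was −0.05 with TMM and 0.09 with library totals, and it moved less between tg and wt.

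Named genes follow a rule set before the gene tables were read: the called genes (12 with the largest rise and 12 with the largest fall, mean of at least 1 CPM in a group), up to 4 members of each list with the smallest p, 5 each way per age comparison, the genes of short list counts, and genes of the transgene constructs, of which App and Prnp are given. Genes outside it are said to be chosen after their values were seen. Statements about what a gene does are background knowledge.

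The alternatives planned before the data were examined were a filter of at least 1 CPM in 4 libraries, no filter, RLE factors, library totals only, DESeq2 1.42.0, limma-voom with quality weights, a score of other cell types as covariate, a replicate block, each library left out in turn, only the libraries compared, camera with an estimated correlation, fry, and a limit of 0.01. Fits without the low-count library for comparisons that it is not part of, list tests without it by camera with an estimated correlation and fry, fits without it and wt 9 months replicate 1, the replicate block for lists by age, and the exact permutation test of list scores were added after the data were seen. The edgeR fit and camera were tested on simulated data. In counts drawn gene by gene from the levels and spread of these data, 200 genes at 10 CPM or more were changed 2-, 4- and 8-fold. Of these edgeR called 32.3%, 83.6% and 98.5% at 6 months and 24.4%, 81.6% and 96.5% at 9 months over 3 runs, with 13 and 21 false calls. At 4 months, where no change was planted, it called 0 genes and camera did not call the test list. Camera called that list in 3 of 3 runs at 6 and at 9 months, where it was planted at 2-fold. These camera calls were at an unadjusted p under 0.05. Genes were drawn independently, so the runs cannot test whether the preset correlation suits these data.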

Results

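Microglia from the hippocampus of male mice were sequenced as bulk RNA after sorting for live CD11b-high, CD45-intermediate, CD49d-negative cells. The mice were transgenic for an amyloid model (tg) or were controls (wt), at 4, 6 and 9 months of age, which gives 6 groups of 4 libraries. The submitters' files per library hold 53700 genes, and all values are counts of sequencing fragments or reads per gene, given as CPM (counts scaled to the library total times its TMM factor). Values with ± are the mean and SD over libraries, and a log2 fold change (log2 FC) is given with its standard error (SE). The labels do not say whether each replicate is a separate animal, so p-values measure the spread between these samples.

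In 23 libraries the total was 8147240 to 14198506 counts, with 14129 to 18821 genes detected. The last library, tg 9 months replicate 4, held 6325 counts in 1663 genes, which is 0.078% of the next lowest total. Its largest entries were Tmem220 (674 counts, 10.7%) and Gm37621 (652 counts, 10.3%), and 1 count in it equals 158 CPM. It stayed in the test because the grouping was fixed before the data were examined, and values without it are printed beside the test. Group means for tg at 9 months are over the 3 remaining libraries.

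**Figure D1:**
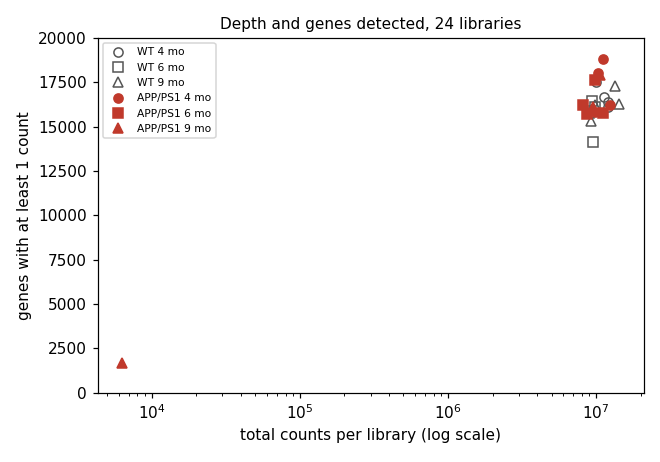
Total counts per library (horizontal axis, log scale) against the number of genes with at least 1 count (vertical axis) for all 24 libraries, with genotype and age in the key. Each point is a library, and tg 9 months replicate 4 (6325 counts, 1663 genes) lies apart from the other 23.

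What differed between tg and wt at 4 months, the youngest age? No gene passed the test, those of disease-associated microglia (DAM, the state described around amyloid plaques) included, and 11 of 28 tested DAM stage 2 genes were higher in tg and 16 lower. Cst7 (ENSMUSG00000068129), which encodes the lysosomal protease inhibitor cystatin F, was at 10.6 ± 3.77 CPM in wt and 12.7 ± 1.94 CPM in tg. The lipid carrier gene Apoe (ENSMUSG00000002985) was at 1010 ± 249 and 1180 ± 294 CPM. The secreted matrix protein gene Spp1 had the smallest p-value of the DAM stage 2 list, at 2.43 ± 1.35 CPM in wt and 9.29 ± 2.82 CPM in tg (log2 FC 1.93, SE 0.68, adjusted p = 1). Neutrophil granule genes were higher in wt: S100a9 was at 10.3 ± 14.3 against 1.39 ± 1.61 CPM, Ngp at 26.7 ± 33.6 against 4.41 ± 5.44 CPM and Camp at 12.6 ± 20.2 against 0.375 ± 0.578 CPM. The transthyretin gene Ttr and the lysophospholipase gene Enpp2, both of the choroid plexus, were higher in tg, at 671 ± 178 against 350 ± 236 CPM and 745 ± 102 against 442 ± 382 CPM. The globin gene Hba-a1 (3.89 ± 2.11 against 0.508 ± 0.272 CPM), the endothelial receptor gene Kdr (4.75 ± 4.22 against 1.02 ± 0.787 CPM) and the tight-junction gene Cldn5 (2.47 ± 0.448 against 0.507 ± 0.851 CPM) were higher in tg too. Of the mitochondrially encoded respiratory genes, mt-Nd1 was at 795 ± 193 CPM in wt and 572 ± 65.5 CPM in tg.

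The edgeR test called 0 of 15156 genes at 4 months, where 379 had an unadjusted p under 0.05 and 758 would by chance. DESeq2 called 3 genes (220 at unadjusted p under 0.05) and limma-voom 0 (861). Camera called 7 of the 31 gene lists with its preset correlation. Higher in tg were choroid plexus (median log2 FC 1.37, adjusted p = 0.00033), vascular cells (0.27, 0.0017) and erythrocytes (1.37, 0.015). Lower were neutrophils (−0.60, 0.00033), mitochondrially encoded genes (−0.37, 0.015), monocytes (−0.41, 0.029) and ribosomal protein genes (−0.17, 0.032). The adjusted p with an estimated correlation was 0.87 for choroid plexus, vascular cells, erythrocytes and neutrophils and 0.99 for the other lists, and fry gave 1 for each. Without the low-count library, which is not in this comparison, camera called 5 lists: choroid plexus higher (0.048), and neutrophils (0.016), mitochondrially encoded (0.00055), ribosomal protein (2.9e-05) and nuclear oxidative phosphorylation genes (4e-04) lower, at adjusted p of 0.63 to 0.82 with an estimated correlation. Without both doubted 9-month libraries it called 4, none of them higher in tg. In the edgeR fit 7 of 7 choroid plexus genes and 14 of 17 vascular genes were higher in tg and 9 of 11 neutrophil genes lower. Adjusted over the list alone, 0 genes of any list were called. Without wt replicate 2 the neutrophil list was at adjusted p = 0.086, and the log2 FC of Camp moved from −5.05 to −2.75 and that of S100a9 from −2.90 to −1.22. Without wt replicate 3 the choroid plexus list was at 0.21. Of 24 fits that each left out a library, the erythrocyte list lost its call in 10 (0.00015 to 0.32) and the ribosomal list in 8 (2.9e-05 to 0.18).

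At 6 months, did the DAM genes differ between tg and wt? Cst7 was at 13.1 ± 0.899 CPM in wt and 169 ± 28.5 CPM in tg, and every tg library lay above every wt library. Its log2 FC of 3.70 (SE 0.71) had an adjusted p of 0.16 in the edgeR fit of all 24 libraries. The planned edgeR fit of only the 8 libraries compared called it, at 3.69 with an adjusted p of 2.8e-05, and so did DESeq2, at 3.71 with 0.0023. Over 21 alternatives the adjusted p ran from 7.4e-40 to 0.73. The phagocytic receptor gene Clec7a (ENSMUSG00000079293) was at 25 ± 7.83 CPM in wt and 84 ± 18.2 CPM in tg (log2 FC 1.75, SE 0.47, adjusted p = 0.82). The growth factor gene Igf1 was at 1.16 ± 1.61 and 18.1 ± 6.75 CPM (3.96, SE 1.28, 0.82) and the lipoprotein lipase gene Lpl (ENSMUSG00000015568) at 20.9 ± 14.7 and 52.8 ± 10.7 CPM (1.34, SE 0.48, 0.84). Apoe was at 1560 ± 503 CPM in wt and 2530 ± 513 CPM in tg (0.70, SE 0.40, 0.98), and the signalling adaptor gene Tyrobp at 939 ± 215 and 1190 ± 140 CPM.

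Genes of other lists did not pass the test at 6 months either. The replication licensing gene Mcm6 was at 36.6 ± 2.32 CPM in wt and 15.4 ± 3.55 CPM in tg (log2 FC −1.24, SE 0.31, adjusted p = 0.75). The mitotic kinase gene Aurkb was at 0.0275 CPM in wt, under the floor of 3 counts, and at 5.45 ± 3.24 CPM in tg. The sorting receptor gene Sorl1 was at 31.3 ± 4.39 and 17.7 ± 4.56 CPM, and the inhibitory receptor gene Cd33 at 390 ± 61.3 and 300 ± 30.5 CPM. Of the genes of border-associated macrophages, Cd209a was at 4.64 ± 3.28 CPM in wt and 20.3 ± 7.87 CPM in tg and F13a1 at 3.76 ± 4.4 and 13.4 ± 13.8 CPM. The glycolytic genes Tpi1 and Ldha were at 85.2 ± 15.4 and 121 ± 7.61 CPM and at 124 ± 7.01 and 168 ± 23.4 CPM. The transcription factor gene Zfp141, chosen after its values were seen, was at 24.3 ± 4.55 CPM in wt and 5.97 ± 3.7 CPM in tg (log2 FC −2.02, SE 0.38, adjusted p = 0.16).

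The edgeR test called 0 genes at 6 months, with 838 at unadjusted p under 0.05, DESeq2 called 14 (562) and limma-voom 0 (687). Without tg replicate 1 edgeR called 1, Zfp141, at a log2 FC of −2.52 (adjusted p = 0.02). Among the DESeq2 calls were Zfp141 (−2.02, 0.016), Fen1 (−1.36, 0.029) and Zfp101 (−1.83, 0.049), chosen after their values were seen. Camera called 2 lists, both higher in tg: DAM stage 2 (median log2 FC 0.50, mean 0.78, adjusted p = 0.0039) and border-associated macrophages (0.72, mean 0.85, 0.0042). Each had an adjusted p = 0.99 with an estimated correlation and 1 by fry. The DAM stage 2 list was at 0.052 without wt replicate 2 and 0.074 without tg replicate 4. Replicate 3 of wt stood apart on the first principal component (147.6, with the other 22 libraries at −36.9 to 33.1), had the fewest genes of the 23 libraries (14129) and a choroid plexus score of −1.38. Without it the DAM stage 2 list was at 0.0012 and the border-associated macrophage list at 0.033, and 0 genes were called by edgeR (956 at unadjusted p under 0.05). In the edgeR fit 20 of the 28 tested DAM stage 2 genes were higher in tg and 8 lower (24 and 4 with library totals). Adjusted over the list alone, 3 of them were called (Clec7a, Cst7 and Igf1), 2 in the proliferation list (Aurkb higher, Mcm6 lower) and 0 in the border-associated macrophage list. F13a1 had a log2 FC of 1.84 with all libraries, 0.84 to 3.10 with single libraries left out.

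At 9 months, were these genes further apart? Cst7 was at 433 ± 61.7 CPM in tg and 86.2 ± 135 CPM in wt, Lpl at 165 ± 16.6 and 29.9 ± 19.1 CPM and the receptor kinase gene Axl at 71.1 ± 11.9 and 12 ± 12 CPM. The actin-capping gene Capg (ENSMUSG00000056737) was at 115 ± 16.8 CPM in tg and 63.9 ± 6.41 CPM in wt. Apoe was at 5420 ± 417 and 2220 ± 967 CPM and the lysozyme gene Lyz2 at 1100 ± 17.5 and 625 ± 123 CPM. Clec7a (203 ± 5.91 against 65.4 ± 64.2 CPM), Igf1 (66.4 ± 19.7 against 5.43 ± 10.1 CPM), Spp1 (70.5 ± 15.6 against 19.5 ± 12.6 CPM) and the integrin gene Itgax (30.7 ± 5.64 against 6.42 ± 7.51 CPM) were chosen after their values were seen. The wide spread in wt comes from wt 9 months replicate 1, at 288 CPM of Cst7 where the other 3 wt libraries were at 11.5 to 29.7 CPM. That library also held 161 CPM of Clec7a (others 22.8 to 43.8), 20.6 CPM of Igf1 (others 0 to 1.12), 58 CPM of Lpl (others 16.1 to 25.1) and 3560 CPM of Apoe (others 1270 to 2160). Of Hbb-bs, a globin gene, it held 0 CPM, where the other wt libraries held 10.6 to 24.2 CPM and tg libraries 0 to 0.212 CPM. Its border-associated macrophage and oligodendrocyte scores (mean log2 CPM 1.60 and 1.07) lay below those of the other 6 deeply sequenced 9-month libraries of both genotypes (2.33 to 3.36 and 1.55 to 2.83).

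Genes of the homeostatic state were lower in tg at 9 months without passing the test. The GTPase gene Rhob was at 219 ± 45.1 against 380 ± 95.8 CPM, the crystallin gene Crybb1 at 218 ± 26.3 against 314 ± 45.6 CPM and the leukotriene synthase gene Ltc4s at 427 ± 23.3 against 615 ± 94.1 CPM. The most used markers of that state, chosen after their values were seen, were at 14200 ± 2400 against 16100 ± 1840 CPM for P2ry12 and 8260 ± 1050 against 9050 ± 964 CPM for Cx3cr1. The DAM receptor gene Trem2, chosen in the same way, was at 2220 ± 83.6 CPM in tg and 2130 ± 229 CPM in wt. Of the interferon-response genes, none of which passed the test, Ifit2 was at 67.3 ± 43.5 CPM in tg and 27.3 ± 17.8 CPM in wt, Usp18 at 39.1 ± 33.1 and 16.1 ± 9.55 CPM and Ifitm3 at 50.9 ± 44.6 and 23.1 ± 10.1 CPM. Replicate 3 of tg carries most of this, with 102 CPM of Ifitm3 (other tg libraries 21.7 and 28.8), and without it the log2 FC of Ifitm3 moved from 1.07 to 0.06. The sterol synthesis gene Hmgcs1 was at 55.7 ± 11.8 CPM in tg and 29.4 ± 9.01 CPM in wt. The spindle gene Tpx2 was at 5.52 ± 3.01 CPM in tg and had 0 counts in all 4 wt libraries. The globin gene Hba-a1 was at 12 ± 12.1 CPM in wt and 0.446 ± 0.439 CPM in tg. Hbb-bs was at 11.6 ± 9.92 CPM in wt and under the floor of 3 counts in tg.

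**Figure D2:**
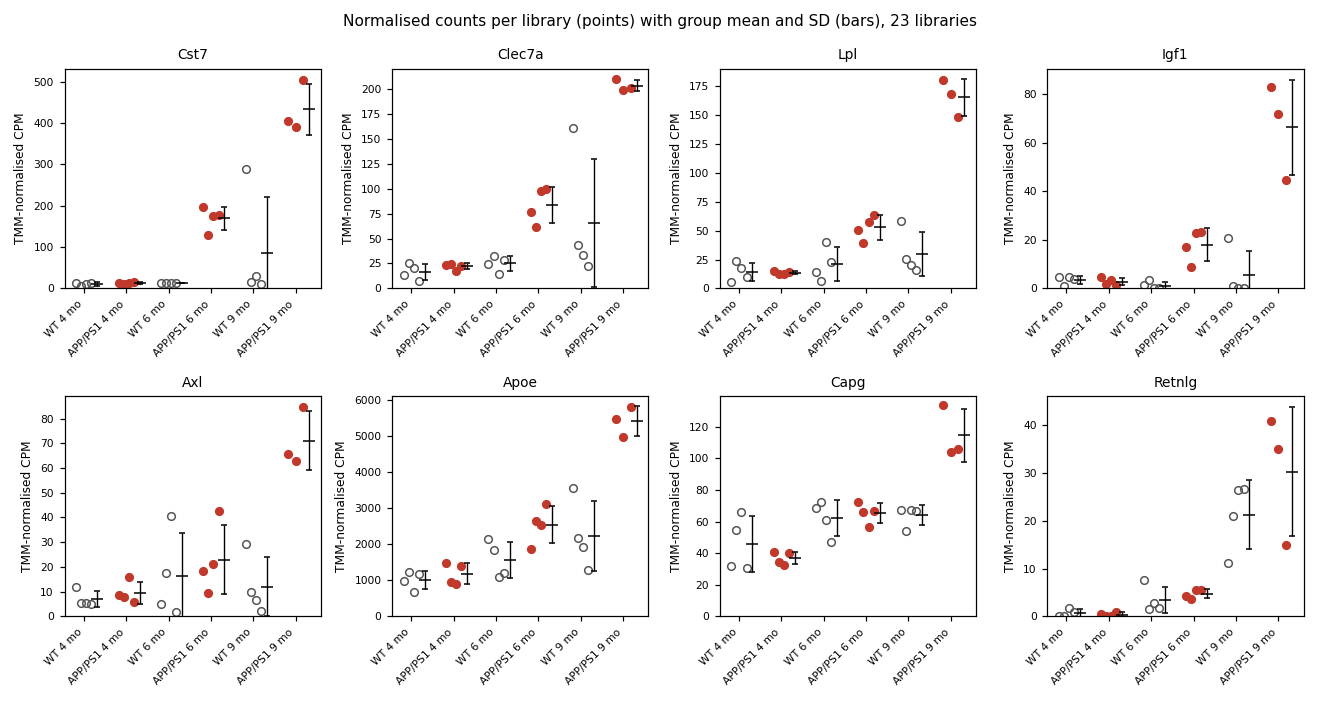
Level in CPM of 8 genes (1 panel each) by age and genotype in 23 libraries, as points with the group mean and SD. Cst7 in tg goes from 12.7 ± 1.94 to 433 ± 61.7 CPM between 4 and 9 months, and wt 9 months replicate 1 lies at 288 CPM.

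The edgeR test called 0 genes at 9 months, with 694 at unadjusted p under 0.05. The smallest p of a DAM gene was that of Lpl (log2 FC 2.36, SE 0.50, adjusted p = 0.62), followed by Capg (0.80, SE 0.22), Axl (2.54, SE 0.76) and Cst7 (2.18, SE 0.67, adjusted p = 1). DESeq2 called 13 genes (549 at unadjusted p under 0.05), among them Lpl (2.32, 0.011). The 6 called by limma-voom with quality weights (1069) include Lpl (2.63, 0.0028), Cst7 (3.67, 0.01), Igf1 (6.73, 0.025) and Axl (2.86, 0.042). Without wt replicate 1 edgeR called 2 genes, Cst7 (4.34, 1.1e-05) and Clec7a (2.48, 0.025). Without tg replicate 1 it called 1, Gm37621, and without tg replicate 2 it called 2, Tcaim and Gm37621. Of these, Gm37621 rests on the low-count library (652 counts, at most 6.22 CPM in any other library). Without wt replicate 1 and the low-count library, a choice made after seeing the data, 4 were called: Cst7 (4.50, SE 0.34, 3.1e-07), Clec7a (2.60, SE 0.37, 0.0055), Lpl (3.01, SE 0.51, 0.041) and Apoe (1.61, SE 0.28, 0.041). That choice is circular for DAM genes, because wt replicate 1 was doubted for its levels of them. Over 20 alternatives, fits with that choice included, the adjusted p ran from 1.8e-46 to 1 for Cst7, 8.9e-07 to 1 for Lpl and 1.4e-05 to 1 for Apoe.

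Camera called 9 lists at 9 months. Higher in tg were DAM stage 2 (median log2 FC 0.02, mean 0.32, adjusted p = 1.5e-07), proliferation (−0.29, mean −0.03, 0.00057), oligodendrocytes (−0.38, mean 0.05, 6e-04), monocytes (0.27, 0.0011), neurons (−0.36, mean −0.23, 0.006), lipid handling (−0.26, mean −0.12, 0.0084) and interferon response (−0.59, mean −0.52, 0.049). Lower were nuclear oxidative phosphorylation genes (−2.00, 0.0057) and erythrocytes (−2.75, 0.006). The −2.00 rests on the low-count library. In the edgeR fit the median of the oxidative phosphorylation list was −0.15 with all 24 libraries and −0.09 without that library. These 9 lists had an adjusted p of 0.87 or 0.99 with an estimated correlation, and fry called none. Median, mean and test differ in sign for 5 of these lists, since camera compares a list with all other genes and most genes have no count in the low-count library. In the edgeR fit 21 of 28 DAM stage 2 genes, 27 of 28 interferon genes and 20 of 26 proliferation genes were higher in tg (27, 27 and 22 with library totals). All 28 homeostatic genes (25 with library totals), all 7 choroid plexus genes and all 6 erythrocyte genes were lower. Adjusted over the list alone, 7 DAM stage 2 genes were called, 1 in lipid handling (Lpl), 1 in proliferation (Tpx2) and 4 in erythrocytes (Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, all lower). Of 24 fits that each left out a library, the interferon list lost its call in 21 (0.00055 to 0.86, the highest without tg replicate 3) and the erythrocyte list in 3 (3.1e-07 to 0.12).

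Without the low-count library alone, 0 genes were called at 9 months (795 at unadjusted p under 0.05), and 27 of 28 DAM stage 2 genes were higher in tg. Adjusted over the list alone, 9 of them were called, and 4 of DAM stage 1 (Apoe, Ctsb, Lyz2 and Tyrobp). In that fit camera called 9 lists. DAM stage 2 (median 0.92, mean 1.51, adjusted p = 3.4e-18), DAM stage 1 (0.29, 0.003), interferon response (0.83, 0.00055), proliferation (0.63, 0.0033), lipid handling (0.26, 0.008), oligodendrocytes (0.40, 0.028) and glycolysis (0.24, 0.044) were higher. Homeostatic genes (−0.19, 7e-04) and erythrocytes (−2.66, 3.8e-05) were lower. With an estimated correlation the adjusted p was 0.22 for DAM stage 2 and erythrocytes, 0.42 for DAM stage 1 and proliferation, 0.46 for lipid handling, 0.60 for homeostatic genes, 0.63 for interferon response and 0.69 for oligodendrocytes and glycolysis, while fry called DAM stage 2 (0.031). The median of the homeostatic list in the edgeR fit was −0.42 with all libraries and −0.18 without the low-count library, where 24 of 28 genes were lower.

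The list scores show the course over the ages. The mean log2 CPM of the DAM stage 2 genes was 4.74 ± 0.20 in wt and 4.78 ± 0.22 in tg at 4 months, 4.97 ± 0.23 and 5.74 ± 0.42 at 6 months, and 5.28 ± 0.88 and 6.79 ± 0.16 at 9 months. The tg minus wt differences were 0.04, 0.78 and 1.51, at exact permutation p = 0.83, 0.057 and 0.057 (adjusted 0.83, 0.13 and 0.13). The smallest p this test can give is 0.029, and it was added after the data were seen. For DAM stage 1 the differences were 0.03, 0.21 and 0.40 (exact p = 0.8, 0.057 and 0.057) and for homeostatic genes −0.02, −0.08 and −0.18 (exact p = 0.71, 0.23 and 0.086).

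**Figure D3:**
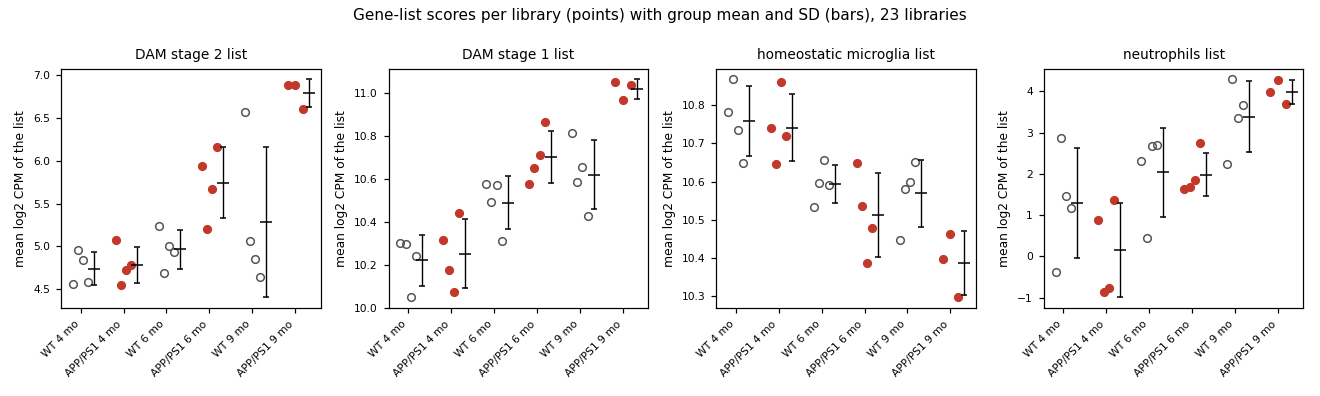
Mean log2 CPM of the genes of 4 lists (1 panel each) by age and genotype in 23 libraries, as points with the group mean and SD. The DAM stage 2 score of tg lies at 4.78 ± 0.22, 5.74 ± 0.42 and 6.79 ± 0.16 at 4, 6 and 9 months.

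Did the difference between tg and wt change with age? The edgeR interaction called 0 genes between 6 and 4 months (541 at unadjusted p under 0.05; DESeq2 5, limma-voom 0), 0 between 9 and 4 months (529; DESeq2 5, limma-voom 0) and 0 between 9 and 6 months (709; DESeq2 6, limma-voom 0). The count was 1 between 9 and 4 months without wt 9 months replicate 1 or tg 9 months replicate 2, and 1 between 9 and 6 months without tg 6 months replicate 1 or tg 9 months replicate 2. Lpl had the smallest p of the DAM genes between 9 and 4 months, at 2.40 (SE 0.69, adjusted p = 1). With both doubted libraries left out, a choice made after seeing the data, Cst7 was called between 6 and 4 months (3.44, SE 0.38, adjusted p = 0.00027) and between 9 and 4 months (4.25, SE 0.42, 3.1e-05). Camera called 10 lists between 9 and 4 months, with a direction relative to the other genes. Astrocytes, interferon response, neurons and oligodendrocytes were called as higher with a negative mean. Higher were DAM stage 2 (median −0.07, mean 0.28, adjusted p = 2.8e-07), monocytes (0.93, 6.8e-06), proliferation (−0.20, mean 0.06, 2e-04), lipid handling (0.09, 0.0015), neutrophils (0.35, 0.0024), astrocytes (−0.10, mean −0.18, 0.012), interferon response (−0.60, mean −0.42, 0.021), neurons (−0.46, mean −0.35, 0.024) and oligodendrocytes (−0.75, mean −0.33, 0.025). Erythrocytes were lower (−4.28, 0.00017). These lists had an adjusted p of 0.12 to 1 with an estimated correlation, and fry called none. The neutrophil list was at 0.087 without wt 4 months replicate 2 and 0.068 without wt 9 months replicate 1. Over all tested genes the tg against wt log2 FC correlated at r = 0.03 between 4 and 6 months, 0.01 between 4 and 9 months and 0.02 between 6 and 9 months, across genes that are not independent replicates. In that fit 18 of 28 DAM stage 2 genes were higher in tg at both 6 and 9 months. As 20 were higher at 6 months and 21 at 9 months, most of this overlap follows from those counts.

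What changed with age in tg? Between 4 and 9 months 5 genes rose in the edgeR test, each at a higher level in all 3 deeply sequenced libraries at 9 months than in all 4 at 4 months. Cst7 went from 12.7 ± 1.94 to 433 ± 61.7 CPM (log2 FC 4.93, SE 0.76, adjusted p = 0.007), with 169 ± 28.5 CPM at 6 months. Lpl went from 13.8 ± 1.31 to 165 ± 16.6 CPM (3.47, SE 0.53, 0.007), Clec7a from 22.1 ± 3.07 to 203 ± 5.91 CPM (3.09, SE 0.5, 0.012) and Capg from 37 ± 3.97 to 115 ± 16.8 CPM (1.59, SE 0.23, 0.0065). The resistin-like gene Retnlg (ENSMUSG00000022651), made by neutrophils, went from 0.346 ± 0.439 to 30.3 ± 13.6 CPM (6.34, SE 1.09, 0.02), with 0 counts in 2 of 4 tg libraries at 4 months. It was higher in wt at 9 months as well, at 21.3 ± 7.27 against 0.642 ± 0.802 CPM at 4 months, which did not pass the test (5.07, SE 1.00, adjusted p = 0.47).

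Without the low-count library, in a fit planned as for every other library, 19 genes were called between 4 and 9 months in tg, 16 up and 3 down. The added genes include Apoe (2.20, SE 0.29, adjusted p = 0.0029), from 1180 ± 294 to 5420 ± 417 CPM, Lyz2 (1.57, 0.017), from 368 ± 105 to 1100 ± 17.5 CPM, and Tyrobp (0.75, 0.046), from 756 ± 106 to 1270 ± 102 CPM. The ferritin gene Fth1 (0.65, 0.017), the glycoprotein gene Cd52 (1.28, 0.036) and Ifitm3 (2.34, 0.036) rose as well. The inhibitory receptor gene Cd300a fell from 289 ± 26.4 to 170 ± 16.5 CPM (−0.76, 0.017), the tetraspanin gene Cd82 from 457 ± 65.8 to 282 ± 27.2 CPM (−0.69, 0.046) and the membrane protein gene Tmem204 from 189 ± 21.9 to 98.1 ± 8.08 CPM (−0.95, 0.046). The remaining 5 are Gvin-ps7 (1.24), Cd63-ps (0.83), Gm13456 (0.66), Ftl1-ps1 (0.61) and Eef1a1 (0.53), of which 4 are pseudogenes or predicted genes by their symbols.

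In this comparison 974 genes had an unadjusted p under 0.05, and DESeq2 called 44 genes and limma-voom 182, with all 5 among both. The count of 5 was 0 without tg 4 months replicate 2 or 3, 1 without replicate 1, and 11, 8 and 19 without tg 9 months replicates 2, 3 and 4. Over the alternatives the adjusted p ran from 1.9e-68 to 0.068 for Cst7, 6e-12 to 0.12 for Lpl, 3.3e-18 to 0.083 for Clec7a, 2.6e-09 to 0.067 for Capg and 2e-08 to 0.15 for Retnlg. These ranges include fits without both doubted libraries, a choice made after seeing the data. In tg 0 genes were called between 4 and 6 months (1438 at unadjusted p under 0.05, smallest adjusted p 0.0871; DESeq2 47, limma-voom 50) and 0 between 6 and 9 months (844, 0.0795; DESeq2 15, limma-voom 2). Without tg 6 months replicate 1 both counts were 1, and between 6 and 9 months it was 2 without tg 9 months replicate 2 and 1 without the low-count library. Camera called 11 lists between 4 and 9 months in tg. Its direction is relative to the other genes, most of which have no count in the low-count library. So oligodendrocytes, proliferation, neurons and DAM stage 1 were called as higher with a negative median and mean. Higher were neutrophils (median 2.26, adjusted p = 7.6e-19), DAM stage 2 (0.82, 7.4e-18), monocytes (0.03, 3.5e-08), interferon response (0.22, 4e-07), astrocytes (−0.01, mean 0.12, 0.00011), oligodendrocytes (−0.27, mean −0.13, 5e-04), lipid handling (−0.33, mean 0.06, 0.00062), proliferation (−0.09, mean −0.28, 0.0018), neurons (−0.27, mean −0.32, 0.0071) and DAM stage 1 (−0.22, mean −0.38, 0.024). Homeostatic genes were lower (−1.18, 0.0028). Their adjusted p with an estimated correlation was 0.07 for neutrophils and monocytes, 0.31 for DAM stage 2 and 0.27 to 1 for the rest. Without the low-count library 12 lists were called. In that fit DAM stage 2 (median 1.71, 2.1e-31), neutrophils (3.86, 4.9e-14) and DAM stage 1 (0.54, 5.5e-09) each had an adjusted p of 0.0079 with an estimated correlation. Interferon response and homeostatic genes lay just under the threshold, at 0.05 after rounding. Without the low-count library the mean log2 CPM of the homeostatic genes in tg was 10.74 at 4 and 10.39 at 9 months. That is a smaller fall than the median of −1.18 with all libraries.

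What changed with age in wt? The edgeR test called 0 genes between 4 and 6 months (1005 at unadjusted p under 0.05; DESeq2 5, limma-voom 0), 0 between 4 and 9 months (888; DESeq2 11, limma-voom 0) and 0 between 6 and 9 months (894; DESeq2 4, limma-voom 0; 1 by edgeR without wt 6 months replicate 1). Camera called 7 lists between 4 and 9 months. Higher were neutrophils (median 2.32, adjusted p = 1.5e-11), erythrocytes (2.48, 5.5e-07), DAM stage 2 (0.33, 0.0021), interferon response (0.46, 0.0048), MHC class II (0.61, 0.024) and DAM stage 1 (0.22, 0.046). The unfolded protein response was lower (−0.18, 0.048). With an estimated correlation the adjusted p was 0.12 for neutrophils, 0.097 for erythrocytes and 1 for the rest. DAM stage 2 was at 0.56 without wt 9 months replicate 1. In wt S100a9 was at 10.3 ± 14.3 CPM at 4 months and 38.9 ± 18.5 CPM at 9 months, and S100a8 at 19.8 ± 26.3 and 60.1 ± 31.8 CPM. Cst7 in wt had a log2 FC of 3.01 (SE 0.70, adjusted p = 0.47) between 4 and 9 months, and 0.85 with both doubted libraries left out.

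The remaining 16 lists were called at no age between tg and wt. Their adjusted p at 4, 6 and 9 months was 0.94, 0.68 and 0.68 for DAM stage 1, 0.9, 0.6 and 0.074 for homeostatic genes, 0.86, 0.90 and 0.86 for orthologues of Alzheimer risk genes, 0.83, 0.82 and 0.65 for complement and Fc receptors, and 0.9, 0.9 and 0.86 for lysosome genes. It was 0.9, 0.9 and 0.86 for MHC class I, 0.49, 0.86 and 0.82 for MHC class II, 0.57, 0.9 and 0.19 for TGF-beta signalling, 0.92, 0.86 and 0.9 for inflammatory genes, and 0.9, 0.94 and 0.86 for glycolysis. It was 0.97, 0.98 and 0.16 for cholesterol synthesis, 0.94, 0.9 and 0.9 for the unfolded protein response, 0.24, 0.94 and 0.95 for immediate early genes, 0.9, 0.25 and 0.25 for circadian genes, 0.19, 0.37 and 0.13 for astrocytes and 0.9, 0.83 and 0.65 for lymphocytes.

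Mouse genes that share sequence with the transgene constructs were compared as a check of the labels. App was at 121 ± 20.7, 139 ± 89.7 and 141 ± 20.5 CPM in wt and 126 ± 15.5, 146 ± 40.3 and 162 ± 5.87 CPM in tg at 4, 6 and 9 months (log2 FC 0.06, 0.07 and 0.15, SE 0.28, 0.28 and 0.30). Without wt 6 months replicate 3, at 273 CPM, the log2 FC of App at 6 months was 0.63. Prnp, whose promoter drives such transgenes, gave −0.18, 0.35 and 0.90 (SE 0.74, 0.73 and 0.77), at 12.4 ± 3.14 CPM in wt and 24.1 ± 5.3 CPM in tg at 9 months. Both had an adjusted p of 1 in the edgeR test. Reads of a human or chimeric transgene need not be counted under mouse genes, so these values do not bear on the labels.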

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

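The tests of exchanged labels, of carry-over and of choroid plexus tissue were chosen after the result was seen, and the test of a tg animal under a wt label and that of the spread were written down before their values were computed. By chance about 5% of groups would hold a library that stands apart, and 15 of 172 tested groups did.

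In wt at 9 months replicate 1 had DAM gene levels near those of tg libraries, with Cst7 at 288 CPM, Clec7a at 161 CPM and Igf1 at 20.6 CPM. Its slope along the DAM stage 2 difference was 0.82. The other wt libraries at 9 months had −0.09 to 0.11 and tg at 9 months 0.98 to 1.03. Those ranges are set by construction, since the difference was taken from the same libraries. Of the libraries outside it, tg at 6 months had 0.28 to 0.72 and wt at 6 months 0.01 to 0.26. Carry-over of reads or amplified cDNA from a single deeply sequenced tg library at 9 months is argued against. At least 6.86% of the genes at 50 CPM or more lay below the level that the needed share would bring. Simulated mixes, with counting error only, gave 0 to 0.159%, and unmixed wt libraries 4.94 to 23.9%. A first form of this test held 0 genes and was replaced by this bound after some values had been seen. Carry-over before amplification, which could add spread beyond counting error, was not simulated. Carry-over from several libraries, from tg libraries of other ages or from the low-count library was not tested. An exchange with tg 9 months replicate 4 stays open, as the log10 likelihood ratio of that library's 143 DAM-list counts was −1.37 (down-sampled wt −6.71 to 2.83, tg −2.31 to 14.7). A tg animal under a wt label also stays open, at a slope of 0.65 over 200 other genes where held-out wt libraries gave 0.39 to 0.73 and tg libraries 0.42 to 0.68, and levels looked at after that go both ways: Hbb-bs was at 0 CPM as in tg (other wt 10.6 to 24.2 CPM), but also under 1 CPM in wt at 4 months, and the oligodendrocyte score of 1.07 lay farther from tg (2.27 to 2.83) than other wt libraries did (1.55 to 2.39). A wt mouse with microglia in this state for another reason, such as an injury or an infection, may explain the levels as well and was not tested.

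No gene was called between tg and wt at any age in the fit of all 24 libraries, at a biological coefficient of variation of 64.6%. Few starting molecules per library and a spread between animals that is the same at all expression levels were considered as explanations. The slope of the squared variation on expression, −0.49 (groups −0.39 to −0.56), lies between what either alone would give. From the lowest to the highest expression levels compared, squared variation beyond counting error fell in every group. It went from 0.289 to 0.0336 in wt at 4 months and from 0.334 to 0.0189 in tg at 9 months. These values argue against a spread that is the same at all levels as the only source. Few starting molecules stay open, and a mix of both was not tested. The coefficient of variation was 67% without the low-count library and 66% without both doubted libraries, while the SE of Cst7 at 6 months went from 0.71 to 0.70 and 0.29, as follows by construction for a gene for which wt 9 months replicate 1 was doubted. For genes without such large changes, small differences between the genotypes stay open too, as 32.3% of simulated 2-fold changes at 6 months were called and 83.6% of 4-fold changes, in genes at 10 CPM or more.

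Within groups, MHC class II scores varied together with choroid plexus scores over 23 libraries (r = 0.63, permutation p = 0.0016, adjusted 0.0064). The rank correlation over these libraries was 0.57, and r without 2 libraries was 0.49. Choroid plexus tissue carried into the sort may bring such cells along, but the choroid plexus score went with that of border-associated macrophages at only r = 0.21 (permutation p = 0.49, adjusted 0.65), which leaves this open. Differences between mice in antigen presentation, or in how the hippocampus was dissected, stay possible and were not tested.

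Replicate 4 of tg at 9 months held 6325 counts in 1663 genes. In wt at 4 months replicate 2 had 42.8 CPM of Camp and 31.6 CPM of S100a9, replicate 1 had 11.9 CPM of Axl and replicate 4 had 0.454 CPM of Hbb-bs. In tg at 4 months replicate 3 had an interferon response score of 2.11. In wt at 6 months replicate 3, apart from all others on the first principal component (147.6), had a border-associated macrophage score of 1.51 and 273 CPM of App, and replicate 2 had 10.3 CPM of F13a1. Replicate 3 of tg at 6 months had 10.3 CPM of Hbb-bs, and replicate 2_4 of wt at 9 months 54.3 CPM of Capg.

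Camera with the preset correlation set some lists apart from the other genes in how the tg against wt difference moved between 4 and 9 months. They were DAM stage 2 (adjusted p = 2.8e-07), monocytes (6.8e-06), erythrocytes (0.00017), proliferation (2e-04), lipid handling (0.0015), neutrophils (0.0024), astrocytes (0.012), interferon response (0.021), neurons (0.024) and oligodendrocytes (0.025). Camera does not ask whether a list itself changed. Astrocytes, interferon response, neurons and oligodendrocytes had a negative mean though they were called as higher. With an estimated correlation 0 lists were called.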

How the results depend on the processing

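Fits without both doubted 9-month libraries, and the estimated correlation without the low-count library, were chosen after the result was seen, and so was the exact test of list scores. The cause of the changed counts below was not tested.

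For tg against wt at 4, 6 and 9 months (0, 0 and 0 genes), DESeq2 called 3, 14 and 13, limma-voom with quality weights 6 at 9 months, and edgeR with only the libraries compared 1 at 6 months. Without both doubted libraries edgeR called 1 and 4 at 6 and 9 months, DESeq2 3, 45 and 43 at the 3 ages, and limma-voom 4 and 17 at 6 and 9 months. For the differences between ages (6 minus 4, 9 minus 4 and 9 minus 6 months, all 0), DESeq2 called 5, 5 and 6, and without both libraries 11, 19 and 29. Without both, edgeR and limma-voom called 1 each for 6 minus 4 and 9 minus 4 months. In wt (6 against 4, 9 against 4 and 9 against 6 months, all 0) DESeq2 called 5, 11 and 4, and 35, 48 and 32 without both libraries, and limma-voom without both 1 at 9 against 4 months. In tg (0, 5 and 0) DESeq2 called 47, 44 and 15, limma-voom 50, 182 and 2, and edgeR without both libraries 3, 16 and 1. DESeq2 without both called 325, 154 and 41 in tg, and limma-voom 69, 254 and 14. The libraries compared alone gave 3 and 16 genes at 6 and 9 against 4 months in tg, library totals 20 and 2 at 9 against 4 and 9 against 6 months, the covariate 1 at 9 against 6 months, and the limit of 0.01 left 3 at 9 against 4 months.

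With a replicate block edgeR called 1 gene at 9 against 4 and 1 at 9 against 6 months in wt, and 1 and 2 at 6 and 9 against 4 months in tg, and camera called 7 lists between tg and wt. In 10 pairs of a tg and a wt library of the same age and number, correlations were −0.159 to 0.023 and 0 passed 0.1. This gives no sign that the numbers pair libraries, but so few pairs cannot exclude it.

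Camera's 18 lists between tg and wt became 0 with an estimated correlation, 0 by fry, and 0 with an estimated correlation and the low-count library left out, where fry called 1 (DAM stage 2 at 9 months). Without both doubted libraries the estimated correlation called 2 lists at 9 months (DAM stage 2 and erythrocytes), and fry 1 at 6 and 4 at 9 months. The 28 lists by age became 0, 0 and 5, and fry without the low-count library called 2 in wt, 7 in tg and 3 for the difference. Directions turned for DAM stage 1 at 4 months (adjusted p = 1.00 without both libraries and 1.00 with an estimated correlation and the low-count library left out), and by fry for DAM stage 1 and interferon response at 9 months (1.00 each). They turned for Prnp at 4 months (0.11 by limma-voom, 0.02 with a replicate block, 0.11 by limma-voom without both). The correlation of tg against wt changes was 0.02 between 4 and 6 months without the low-count library or both, and 0.00 between 6 and 9 months without the low-count library.

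Leaving out each library in turn gave 0 to 0, 0 to 1 and 0 to 2 genes between tg and wt at 4, 6 and 9 months. It gave 0 to 0, 0 to 1 and 0 to 1 for the differences, 0 to 0, 0 to 0 and 0 to 1 in wt and 0 to 1, 0 to 19 and 0 to 2 in tg. There were 12 to 19 lists between tg and wt and 22 to 32 by age. Adjusted p ranged from 0.68 to 0.99, 0.00058 to 0.074 and 3.4e-18 to 0.00076 for DAM stage 2 at 4, 6 and 9 months, 0.89 to 0.99, 0.18 to 0.86 and 0.003 to 0.9 for DAM stage 1, and 0.71 to 0.96, 0.17 to 0.85 and 0.0007 to 0.19 for homeostatic genes. At 4 months the direction turned without wt replicate 2 for DAM stage 2 (0.99) and homeostatic genes (0.96), and for DAM stage 1 without wt replicate 3 (0.89), tg replicate 4 (0.93) or the low-count library (0.99). It was 0.00015 to 0.32 for erythrocytes at 4 months and 3.1e-07 to 0.12 at 9 months, 0.00055 to 0.86 for interferon response at 9 months, 0.0018 to 0.047 for border-associated macrophages at 6 months. At 4 months it was 2.4e-07 to 0.086 for neutrophils, 1.4e-05 to 0.21 for choroid plexus and 2.9e-05 to 0.18 for ribosomal proteins. Between 4 and 9 months it was 0.00017 to 0.56 in wt, 2.1e-31 to 2e-10 in tg and 1.1e-14 to 0.00022 for the difference for DAM stage 2. It was 3.4e-17 to 2.6e-06, 2.4e-19 to 4.2e-12 and 0.00011 to 0.087 for neutrophils, and 1e-15 to 0.00056 in wt and 4.6e-10 to 0.013 for the difference for erythrocytes.

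The log2 FC over the same fits was −0.03 to 0.15, −0.11 to 0.63 and 0.05 to 0.21 for App at the 3 ages and −0.41 to 0.29, −0.17 to 0.86 and 0.70 to 1.03 for Prnp. For the DAM genes and Retnlg it kept its sign at 6 months (Cst7 3.63 to 3.81, Clec7a 1.56 to 1.91, Igf1 3.55 to 5.42, Lpl 1.04 to 1.87, Apoe 0.56 to 0.89), at 9 months (Cst7 1.81 to 4.34, Lpl 2.16 to 2.90, Capg 0.66 to 0.84, Axl 2.19 to 3.47, Apoe 0.77 to 1.28) and between 4 and 9 months in tg (Capg 1.45 to 1.63, Lpl 3.36 to 3.59, Cst7 4.76 to 5.09, Clec7a 3.00 to 3.20, Retnlg 5.92 to 7.40). Depth sets a floor of 0.211 to 0.368 CPM in 23 libraries. Of simulated 2-fold changes in genes at 10 CPM or more, 32.3% were called at 6 months and 24.4% at 9 months. These shares may be too high for the real data, as genes were drawn independently.

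Among the 35 splits of the tg libraries at 4 and 9 months the real one gave 5 genes and the highest other 0. Without the low-count library these values were 19 and 1. Only the real split reached its count, and 1 of 35 is the smallest share this test can give. The other comparisons were split as well, with no adjustment, so chance is not excluded for these counts. For the counts of 0, all 35 splits (60 drawn for the differences between ages) are as large and exclude nothing, with highest other values of 1, 3 and 6 between tg and wt at 4, 6 and 9 months, 2, 2 and 1 for the differences, 2, 0 and 4 in wt, and 1 and 1 in tg. Without both doubted libraries chance cannot be excluded for 1 gene at 6 months (6 of 35 splits as large, highest other 2), and 10 splits are too few for the 4 genes at 9 months.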

Other observations

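The comparisons given here were looked for after the result was seen.

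The mean log2 CPM of the neutrophil list was higher at 9 than at 4 months in both genotypes. The sort was for CD11b-high, CD45-intermediate, CD49d-negative cells. Of the neutrophil genes only Retnlg passed the edgeR test, and only in tg. Retnlg was at 0.642 ± 0.802 CPM in wt at 4 months and 21.3 ± 7.27 CPM at 9 months, and S100a8 at 3.31 ± 4.13 and 86.4 ± 22.7 CPM in tg. The neutrophil list was called between 4 and 9 months in wt (adjusted p = 1.5e-11, 0.12 with an estimated correlation) and in tg (7.6e-19, 0.07). The labels give no sorting day, so age and handling cannot be told apart.

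The globin gene Hba-a1, which passed the edgeR test with all 24 libraries at neither age, was at 0.508 ± 0.272 CPM in wt and 3.89 ± 2.11 CPM in tg at 4 months and at 12 ± 12.1 and 0.446 ± 0.439 CPM at 9 months. Of 6 tested erythrocyte genes 4 were higher in tg and 2 lower at 4 months, and all 6 were lower at 9 months. Camera set the erythrocyte list apart from the other genes in the difference between those ages, at an adjusted p of 0.00017 (0.25 with an estimated correlation).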
